A study of Mus musculus with 12 samples.

How the data were processed

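RNA from mouse hearts was profiled on 12 Affymetrix mouse Gene 1.0 ST arrays, 4 from control mice, 4 from mice carrying mutant IDH2 R140Q and 4 from mice carrying mutant IDH2 R172K. Each array is labelled as a separate replicate. The labels do not say in so many words that each came from a separate animal, so p-values measure the spread between these samples. All mice are of a mixed background of 3 inbred strains. Per the labels' protocols, mutant mice received 2 mg of 4-hydroxytamoxifen, a drug commonly used to switch on Cre recombinase, on 3 days, when they were 5 weeks old. What control mice received, the time from treatment to dissection and the sex of the mice are not given in the sources used here.

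The deposited table holds one RMA intensity per probe set and array, processed by the authors with RMA, per the submitters' processing notes. RMA subtracts background, sets the arrays to a common distribution and summarises the probes of a transcript. Its version and the annotation are not given in the sources used here. The deposited intensity is on a linear scale, as judged from its values: array medians lay between 74.8 and 78.0 and the highest value was 17591. The test had been planned for log2 values, so log2 of each intensity was taken, with no pseudocount because every value was above 0. No detection calls are used, so dim genes stayed in the tests and a low value may lie at the background of the array. RMA sets all arrays to a similar distribution, so a change shared by most genes cannot be seen in these values.

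Of 34760 probe sets, 21640 carried 1 gene symbol in the platform's probe table, 1321 carried several and 11799 were not listed there. Probe sets with 1 symbol gave 19937 genes, and the remaining 13120 probe sets were kept out of all named results. Gene IDs of 21553 probe sets matched the gene table of assembly GRCm38.p6, and no symbol had to be updated. Where a gene had more than 1 probe set, as 954 genes did, the probe set with the highest mean over all 12 arrays stood for it. Control probe sets could not be recognised by name, so the use of probe sets with 1 symbol took the place of leaving them out.

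Group means of the 12 arrays were fitted together for each gene with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), so that the 3 groups share one estimate of the spread. The fit had 9 residual degrees of freedom, and eBayes added 3.54. Contrasts compared each mutant with control, R172K with R140Q, and the mean of both mutants with control. Adjusted p-values of genes are Benjamini-Hochberg values over the 19937 genes of a contrast unless another set is given. A gene counted as changed at an adjusted p under 0.05. Fits to every probe set, or without the dimmer genes, were adjusted over the probe sets or genes they held. Errors of log2 differences are limma's moderated standard errors (SE), and group values are means ± SD of 4 arrays. The number of arrays limits the precision. On simulated data with 50 genes changed by each fold size, the fit recovered 80% of the 1.5-fold changes and 98% of the 2-fold changes for R140Q against control, with 7 false calls among 196. For R172K against control it recovered 82% and 90%, with 8 false calls among 194. The simulation drew noise independently for each gene, with the same SD in all arrays. Quality weights estimated for the real arrays ran from 0.365 to 1.962, so these rates may not hold for the real data.

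Gene lists for cardiac pathways and for markers of the cell types that a heart sample can hold numbered 38, and 37 of them had at least 5 genes measured. Of 811 genes written in them, 755 were measured. Lists were tested with limma's camera at its preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 37 lists of a contrast. Camera with a correlation estimated for each list was the alternative. List members were also counted with adjusted p-values taken over the list alone. The groups, contrasts, tests, thresholds, gene lists, most alternatives and the rule for naming genes were chosen before the data were examined.

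The rule named, per contrast, the 10 largest higher and 10 largest lower log2 differences among changed genes whose groups did not overlap, leaving out predicted genes, clone names and unnamed probe sets. It also named up to 4 members of each described list with the smallest p, and always Idh2 and the sex-linked genes. Members that passed the test beyond these 4, and genes given for the tissue they mark, were chosen after their values were seen.

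Alternatives covered the arrays in the fit, the replicate number as a block, the choice of probe set, a filter on dim genes, normalization, the variance model, array weights, stricter thresholds and each array left out in turn. Added after seeing the data were a fit without the 3 arrays highest in atrial or lung markers (control 3, R172K 3 and R140Q 4) and a fit with Myl7 intensity as a covariate. The closest pair of arrays, control 1 and control 2, still differed with an SD of 0.166 in log2 over all genes, so all 12 arrays were counted. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.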

Results

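Gene expression in the heart was compared between control mice and mice that carried a mutant form of IDH2, the mitochondrial isocitrate dehydrogenase. Both mutant forms studied, R140Q and R172K, are known to convert 2-oxoglutarate to D-2-hydroxyglutarate. The series concerns cardiomyopathy in mice with mutant IDH2. Each of the 3 groups held 4 arrays, and 19937 genes were tested. Array medians ranged from 74.8 to 78.0 intensity units.

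Idh2 itself was bright in all hearts. Its log2 intensity was 12.74 ± 0.11 (SD, n = 4) in control, 12.45 ± 0.14 in R140Q and 12.38 ± 0.33 in R172K hearts. The differences of -0.30 for R140Q (limma adjusted p = 0.301) and -0.36 for R172K (adjusted p = 0.109) did not pass the test. Without R172K 4 the R172K difference was -0.195 (adjusted p = 0.182), and the difference between the mutants, -0.07 (adjusted p = 0.887), became 0.101 (adjusted p = 0.633). Whether the probe set reads the mutant transcript is not given in the sources used here, so these values do not check the labels. Xist, the RNA of the inactive X chromosome, lay at 3.92 in control, 3.86 in R140Q and 4.01 in R172K hearts, while the Y-linked Eif2s3y lay at 9.45, 9.59 and 9.82.

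The first principal component held 40.7% of the variance. It placed the control arrays between -26.88 and -17.09, the R140Q arrays between -2.61 and 11.15, and the R172K arrays between -6.19 and 40.75. R172K replicate 3, at -6.19, lay nearest the control arrays, and R172K replicate 4, at 40.75, lay farthest from them.

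**Figure D1:**
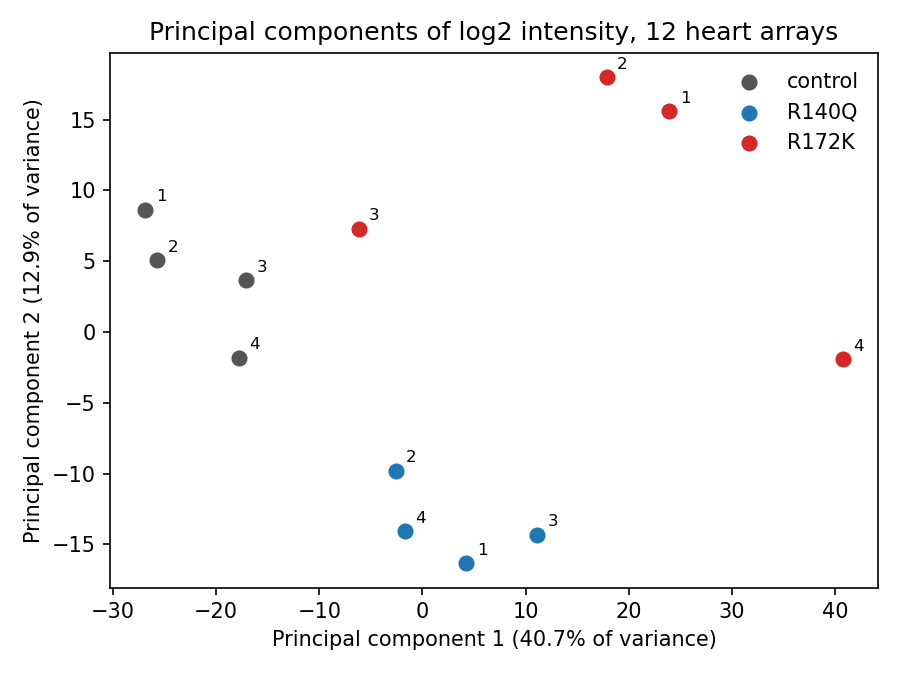
Scores of the 12 arrays on the first 2 principal components of log2 intensity, with axes giving the percent of variance and numbers giving the replicate. Control arrays lie between -26.88 and -17.09 on the first component, and R172K arrays spread from -6.19 to 40.75.

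The first comparison asked what differed between R140Q and control hearts. The labels give hydroxytamoxifen treatment for mutant mice only. In every contrast with control, an effect of this drug or of Cre therefore cannot be told apart from one of the mutation. Natriuretic peptide B (Nppb), a hormone gene induced in stressed heart muscle, rose by 2.15 ± 0.27 (SE) in log2 (limma adjusted p = 0.00394). Skeletal muscle actin (Acta1), which belongs to the fetal heart program, rose by 1.48 ± 0.16 (adjusted p = 0.00281). The nicotinamide riboside kinase gene Nmrk2, active in NAD synthesis, rose by 3.25 ± 0.69 (adjusted p = 0.0335), with a wide spread among R140Q hearts (10.77 ± 1.93 against 7.53 ± 0.14 in control). The amino acid transporter gene Slc38a4 fell by 2.24 ± 0.22 (adjusted p = 0.00281), and Phkg1, the muscle catalytic subunit of phosphorylase kinase, fell by 1.76 ± 0.27 (adjusted p = 0.00639).

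In all, 439 genes changed between R140Q and control hearts, 216 higher and 223 lower, and 55 of them by at least 2-fold. Other genes among the largest increases were the F-box gene Fbxo44 (1.86), the MYB family gene Mybl1 (1.55), the syntrophin gene Sntb1 (from 8.15 in control to 9.65), the uridine-cytidine kinase gene Uck2 (1.47), the ketone body enzyme gene Bdh1 (1.36) and the single-stranded DNA binding gene Nabp1 (1.26). Large decreases included Lgi1 (-2.34), Cabcoco1 (-2.23), the tropomodulin gene Tmod4 (-2.14), the coagulation inhibitor gene Tfpi (-1.77), the galactosyltransferase gene B3galt2 (-1.62), Armh4 (-1.60), the glutamine transporter gene Slc38a1 (-1.54) and the monoamine oxidase gene Maob (-1.49).

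Cardiac stress and fetal genes rose as a list in R140Q hearts (camera adjusted p = 0.00572; adjusted p = 0.628 with an estimated correlation). Of 14 members, 4 rose and none fell, with 6 higher and 1 lower when adjusted over the list alone. Beside Nppb and Acta1, these were the actin-binding repeat gene Xirp2 (0.84) and the ankyrin repeat gene Ankrd1 (0.67). Extracellular matrix genes had a mean difference of 0.62 (camera adjusted p = 8.73e-09; adjusted p = 0.628 with an estimated correlation), but only 2 of 44 rose, the basement membrane collagens Col4a1 (0.93) and Col4a2 (0.91), and Thbs2 fell by 0.55. Adjusted over the list alone, 10 were higher and 1 lower. Endothelial markers were higher (mean 0.30, camera adjusted p = 2.62e-09; adjusted p = 0.0641 with an estimated correlation), and 5 of 22 rose, among them the endothelial cadherin Cdh5 (0.45), the VEGF receptor Kdr (0.45), Esam (0.49) and Flt4 (0.42), with 12 higher when adjusted over the list alone.

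Calcium handling and ion channel genes were lower in R140Q hearts (mean -0.26, camera adjusted p = 0.000135; adjusted p = 0.628 with an estimated correlation). The pacemaker channel gene Hcn4 fell by 0.96 and the inward rectifier potassium channel gene Kcnj2 fell from 8.65 to 7.64, while the other 21 of 23 did not pass, and 5 were lower when adjusted over the list alone. Fatty acid oxidation genes had a mean of -0.23 (camera adjusted p = 0.000135; adjusted p = 0.628 with an estimated correlation), yet none of its 29 members passed by either adjustment, and 3 of them had a positive difference. Without R140Q 3 the mean of that list was -0.14. Tricarboxylic acid cycle genes were also lower as a list (mean -0.10, camera adjusted p = 0.00893, or 0.628 with an estimated correlation). None of 21 passed, and 1 was higher when adjusted over the list alone. That call ended without R140Q 4 (camera adjusted p = 0.0586) or without control 3, R172K 3 and R140Q 4 together (0.059). None of 72 oxidative phosphorylation genes passed by either adjustment (mean -0.08, camera adjusted p = 0.00136; adjusted p = 0.628 with an estimated correlation). Cardiomyocyte markers were lower as a list (mean -0.13, camera adjusted p = 0.0261; adjusted p = 0.628 with an estimated correlation), with none of 16 members passing and 1 lower when adjusted over the list alone.

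Glycogen genes moved in both directions in R140Q hearts and were not called as a list (camera adjusted p = 0.231). The glycogen-targeting phosphatase subunit Ppp1r3c (0.89), the UDP-glucose pyrophosphorylase gene Ugp2 (0.88) and Phka1 (0.50) rose, Phkg1 fell, and 20 of 24 did not pass, with 6 higher and 3 lower when adjusted over the list alone. Among genes of hydroxyglutarate and glutamate metabolism, the alanine transaminase gene Gpt2 fell by 1.10 and the branched-chain transaminase gene Bcat2 by 0.62, with 13 of 15 not passing (camera adjusted p = 0.0334; adjusted p = 0.628 with an estimated correlation). Adjusted over that list alone, 1 was higher and 2 lower, and the call ended without control 4 (adjusted p = 0.0898), R140Q 1 (0.056) or R140Q 4 (0.0626), or without control 3, R172K 3 and R140Q 4 together (0.059). The NRF2 target genes Srxn1 (1.07) and Txnrd1 (0.67) rose, 18 of 20 did not pass, and the list was called higher (camera adjusted p = 0.021; adjusted p = 0.628 with an estimated correlation), with 6 higher and 1 lower when adjusted over the list alone, a call that ended without control 4 (0.0588), R140Q 1 (mean 0.09, adjusted p = 0.167) or the dimmer genes (0.109). Atrial myocardium markers were lower as a list (mean -0.85, camera adjusted p = 0.0392; adjusted p = 0.628 with an estimated correlation). None of its 13 members passed, 4 were lower when adjusted over the list alone, and Myl7, the atrial myosin light chain gene, differed by -3.52 (limma adjusted p = 0.109) with 12.49 in control replicate 3 and 6.18 in control replicate 2. The atrial call ended without control 3 (mean -0.41, adjusted p = 0.475), R140Q 2 (0.153), R140Q 4 (0.0528), the dimmer genes (0.0847) or control 3, R172K 3 and R140Q 4 together (0.137). It also ended with the intensity of Myl7, itself a member of the list, as a covariate (mean -0.309, camera adjusted p = 0.336).

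The R140Q count moved with the arrays in the fit, where R172K arrays enter only through the shared estimate of the spread. It was 1015 without R172K 3 and 982 without R172K 4. Without control 1, 2 and 3 it was 100, 154 and 160. It was 141, 110 and 260 without R140Q 1, 3 and 4, and 289 without R172K 1. Of the 20 genes with the largest changes, 9 passed whichever array was left out, while 11, 7, 7 and 5 failed without control 1, 2, 3 and 4, 8, 2, 11 and 3 without R140Q 1, 2, 3 and 4, and 3 and 2 without R172K 1 and 2, and Nmrk2 failed without any 1 control array, R140Q 1, 2 or 3, or R172K 1 (adjusted p from 0.0505 to 0.0997). The count was 1342 with the 8 arrays alone and 113 with Myl7 intensity as a covariate. With each array centred on its median, the split was 288 higher and 185 lower in place of 216 and 223.

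**Figure D2:**
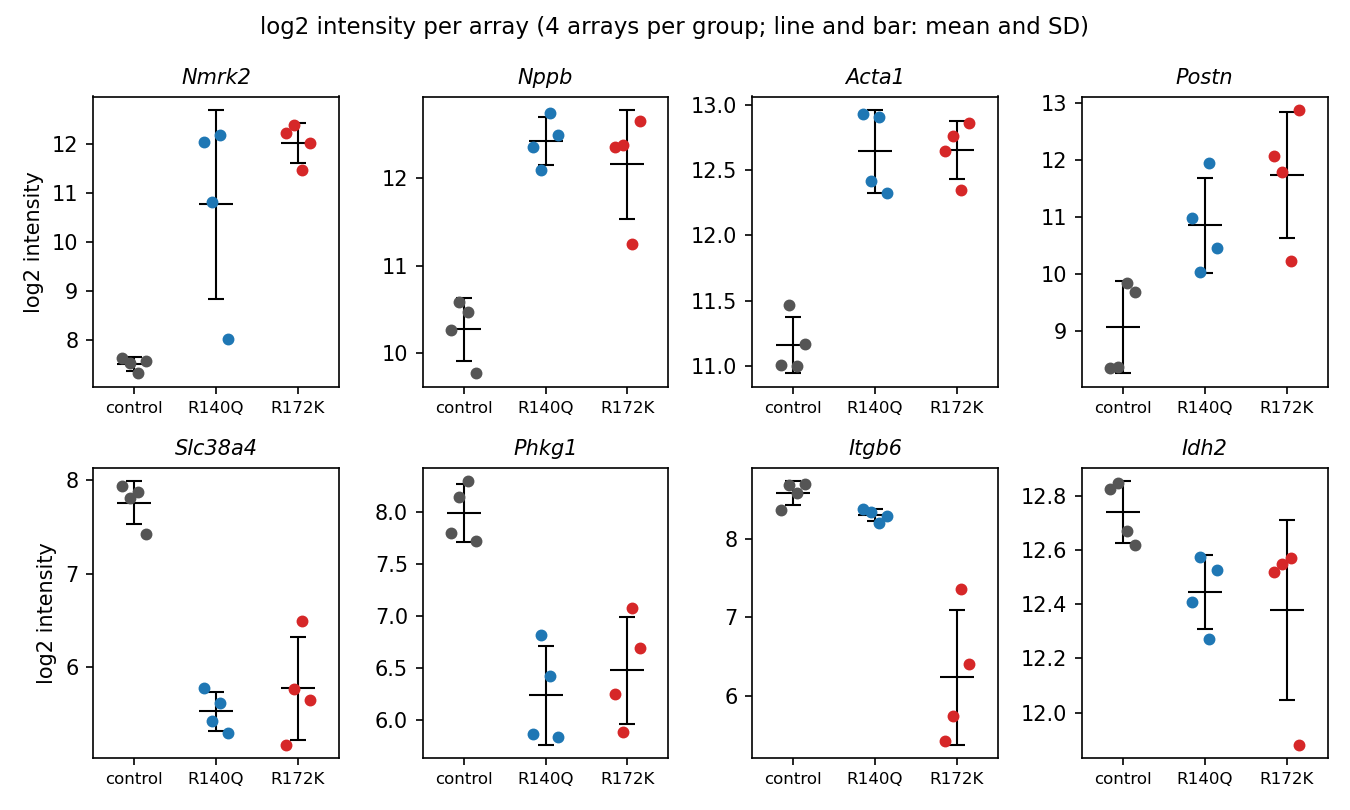
Log2 intensity (vertical axes, which do not start at 0) of 8 genes in each of the 12 arrays, with points for arrays and a line and bar for the mean and SD of 4 arrays per group. Nppb averages 10.27 in control, 12.42 in R140Q and 12.16 in R172K hearts, and Itgb6 averages 8.58, 8.31 and 6.23.

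The same question was put to R172K hearts. Nmrk2 showed the largest increase named, 4.51 ± 0.69 (limma adjusted p = 0.0027). Genes of the extracellular matrix rose with it, including the metalloproteinase inhibitor Timp1 (3.57 ± 0.62, adjusted p = 0.00442), the collagen cross-linking enzyme Lox (3.36 ± 0.60, adjusted p = 0.00508), tenascin C (Tnc, 2.69 ± 0.54, adjusted p = 0.00871) and periostin (Postn, 2.68 ± 0.56, adjusted p = 0.00968). The largest decreases included the carboxylesterase Ces1d, which fell by 3.51 ± 0.81 (adjusted p = 0.0153), the skeletal muscle calsequestrin Casq1, which fell by 2.59 ± 0.52 (adjusted p = 0.00825), and the arsenic methyltransferase As3mt, which fell by 2.21 ± 0.20 (adjusted p = 5e-04).

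Between R172K and control hearts 2593 genes changed, 1242 higher and 1351 lower, and 242 by at least 2-fold. Further large increases were the small proline-rich protein gene Sprr1a (2.72), thrombospondin 1 (Thbs1, 2.37), the collagen gene Col8a1 (2.29), the secreted Wnt antagonist Frzb (2.28) and the microfibril gene Mfap5 (2.27). Further large decreases were Cabcoco1 (-2.87), Lgi1 (-2.75), the integrin subunit Itgb6 (-2.35), the ankyrin repeat gene Asb15 (-2.20), Slc38a4 (-1.99), Klhdc1 (-1.98) and the secretoglobin gene Scgb1c1 (-1.96). Of the sex-linked genes, Eif2s3y rose by 0.37 (adjusted p = 0.0109) and Uty fell by 0.32 (adjusted p = 0.00911).

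Of 44 extracellular matrix genes measured in R172K hearts, 25 rose, none fell and 19 did not pass, with a mean difference of 1.19 (camera adjusted p = 4.99e-17; adjusted p = 0.546 with an estimated correlation), and 34 were higher when adjusted over the list alone. Col4a2 (1.01), Col4a1 (0.99), Mfap5 and Timp1 had the smallest p. Resting fibroblast markers, 6 of which belong to another list as well, were higher (mean 0.47, camera adjusted p = 0.0116; adjusted p = 0.667 with an estimated correlation). Of 21, 7 rose, such as Pdgfra (0.62) and Fbln2 (1.29), and 2 fell, with 9 higher and 2 lower when adjusted over the list alone. Macrophage markers were higher (mean 0.45, camera adjusted p = 0.000687; adjusted p = 0.667 with an estimated correlation), and Fcgr3 (1.09), the cathepsin Ctss (1.21) and the chemokine receptor Ccr2 (1.20) rose among 25, by either adjustment. Epicardial and mesothelial markers were higher (mean 0.42, camera adjusted p = 0.00723; adjusted p = 0.546 with an estimated correlation), with Cldn15 (0.85), Msln (0.70) and Aldh1a2 (1.79) rising among 12, and 4 higher when adjusted over the list alone. Without R172K 4 the camera adjusted p was 0.104 for fibroblast markers and 0.104 for macrophage markers, whose mean was then 0.20. Without the dimmer genes it was 0.07 for fibroblast markers.

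Calcium handling and ion channel genes were lower in R172K hearts (mean -0.43, camera adjusted p = 1.17e-07; adjusted p = 0.546 with an estimated correlation). Of 23, 14 fell and none rose, by either adjustment. The potassium channel genes Kcnd3 (-0.37), Kcnd2 (from 9.38 in control to 8.38) and Kcnh2 (-0.70) and the pacemaker channel gene Hcn4 (-0.91) had the smallest p. Oxidative phosphorylation genes were lower (mean -0.19, camera adjusted p = 2.21e-08; adjusted p = 0.667 with an estimated correlation). Of 72, 22 fell, 1 rose and 49 did not pass, with examples in Cox6a2 (-0.45), Atp5g2 (-0.41), Ndufa2 (-0.60) and Cox7a1 (-0.79), and adjusted over the list alone 33 were lower and 3 higher. Without R172K 4 the mean of that list was -0.12. Cardiomyocyte markers, 10 of which belong to another list as well, were lower (mean -0.24, camera adjusted p = 0.000135; adjusted p = 0.546 with an estimated correlation). The 7 of 16 that fell included the ventricular light chain Myl2 (-0.54), the ryanodine receptor Ryr2 (-0.49) and phospholamban (Pln, -0.26), and 9 were lower when adjusted over the list alone.

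Tricarboxylic acid cycle genes were lower as a list (mean -0.16, camera adjusted p = 0.00779; adjusted p = 0.719 with an estimated correlation), with 6 of 21 lower, such as Sdhc (-0.42), Fh1 (-0.52) and Pcx (-0.62), and 2 higher, among them Pdhb (0.58). Adjusted over the list alone, 8 were lower and 2 higher. Fatty acid oxidation genes were lower as well (mean -0.17, camera adjusted p = 0.0457, or 0.828 with an estimated correlation). Of 29, 5 fell and 1 rose by either adjustment. That call held in 9 of 19 alternatives other than the estimated correlation, and without R172K 4 the mean was -0.038 (camera adjusted p = 0.717). Mitochondrial biogenesis and dynamics genes were lower (mean -0.22, camera adjusted p = 0.0172; adjusted p = 0.667 with an estimated correlation), with 6 of 23 lower and 1 higher, and 8 lower and 1 higher when adjusted over the list alone. Without R172K 4 the camera adjusted p was 0.147 for the tricarboxylic acid cycle (mean -0.08) and 0.113 for mitochondrial biogenesis (mean -0.145), which was 0.051 without control 2 and 0.0526 without the dimmer genes. The genes of the latter list included Tfb1m (-1.13), the lipid-sensing receptor Ppara (-0.96) and the mitophagy kinase Pink1 (-0.68). The stress and fetal list was higher (mean 0.56, camera adjusted p = 0.00323; adjusted p = 0.546 with an estimated correlation), with 6 of 14 higher, led by Acta1 (1.49) and Nppb (1.89), and Mybpc2 lower (-1.32), and 7 higher and 1 lower when adjusted over the list alone. Glycogen genes were not called as a list (camera adjusted p = 0.703): 6 rose and 7 fell by either adjustment, with Phkg1 (-1.52), Ppp1r3b (-0.59) and Phkb (-0.48) among the latter. Of the hydroxyglutarate and glutamate list, Gpt2 (-1.54), Bcat2 (-0.83), the proline pathway enzyme Aldh4a1 (from 8.86 in control to 7.86) and D2hgdh (-0.78), the enzyme that oxidises D-2-hydroxyglutarate, fell, and 1 of 15 rose. That list was not called (camera adjusted p = 0.372), its mean of -0.21 and its median of 0.04 differ in sign, and 3 were higher and 4 lower when adjusted over the list alone.

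The R172K count was 4157 without R172K 3, 1327 without R172K 1, 1559 without control 1 and 1480 without control 2. It was 1788 with the control and R172K arrays alone. Of the 20 genes with the largest changes 18 passed whichever array was left out. Thbs1 (adjusted p up to 0.124) failed without control 1, 2 or 3, R140Q 1 or 3, or R172K 1, 2 or 4, and Ces1d failed without R172K 1 (adjusted p = 0.0513).

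**Figure D3:**
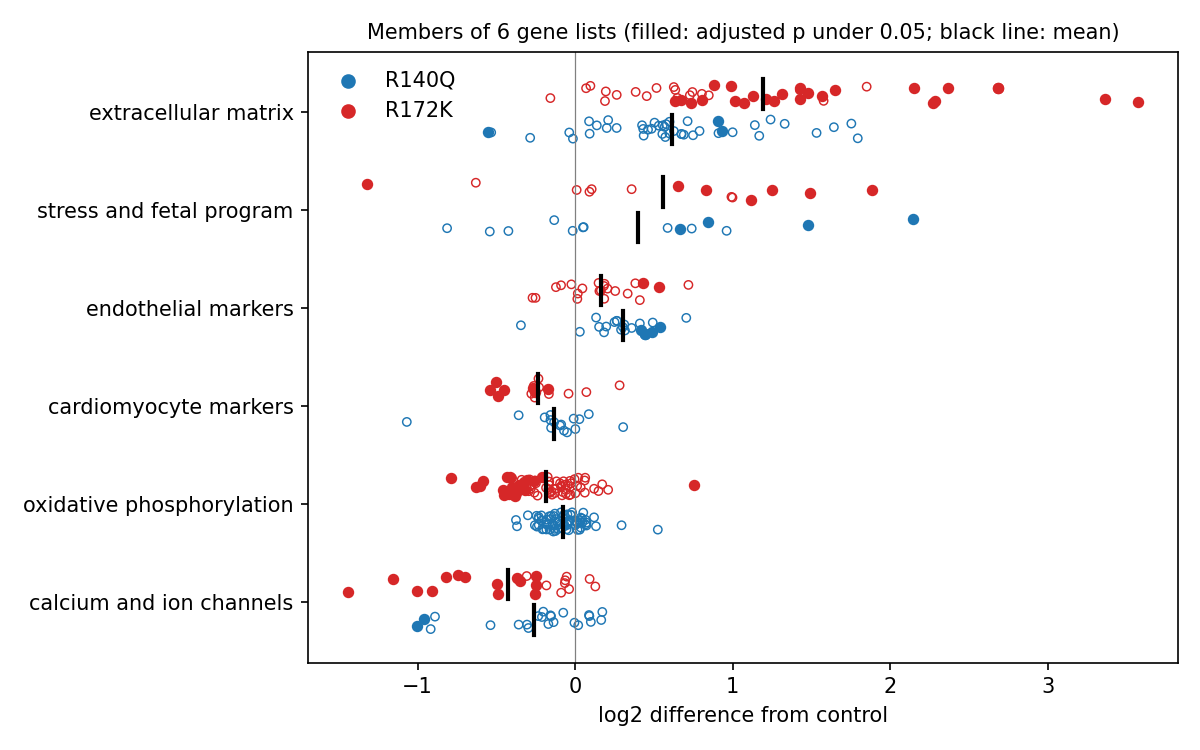
Log2 difference from control (horizontal axis) of the members of 6 gene lists in R140Q (blue) and R172K (red) hearts, with filled points for genes at an adjusted p under 0.05 and a black line for the mean. In R172K hearts 25 of 44 extracellular matrix genes rose and 14 of 23 calcium and ion channel genes fell.

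The contrast of R172K with R140Q hearts tested the difference between the mutants directly. Myl4, the atrial essential light chain of myosin, was higher in R172K by 3.52 ± 0.76 (limma adjusted p = 0.0458), with control hearts at 10.71 ± 2.04 (SD, n = 4), R140Q at 8.37 ± 0.47 and R172K at 11.89 ± 0.64. Sprr1a was higher by 2.27 ± 0.48 (adjusted p = 0.0452) and the liver secreted protein gene Ahsg by 1.88 ± 0.35 (adjusted p = 0.0317). Itgb6 was lower by 2.07 ± 0.31 in log2 (-2.07, adjusted p = 0.0207), and the heat shock protein gene Hsph1 by 1.75 ± 0.22 (-1.75, adjusted p = 0.0131).

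Between the mutants 296 genes differed, 97 higher and 199 lower in R172K. Other genes higher in R172K were Slc38a1 (1.41), Fam122b (1.37), the imprinted gene Peg3 (1.36), Ms4a4a (1.23), the olfactory receptor gene Olfr920 (1.22), the uroplakin gene Upk1b (1.16) and the phospholipase Pla2g7 (1.01). Genes lower in R172K included Plaat1 (-1.72), Fam81a (-1.28), Cfap20dc (-1.26), Morn2 (-1.19), Ky (-1.13), the water channel Aqp8 (-1.05), Sh3bgr (-0.96) and cyclin D2 (Ccnd2, -0.96).

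Extracellular matrix genes were higher in R172K than in R140Q hearts as a list (mean 0.58, camera adjusted p = 1.28e-07; adjusted p = 0.619 with an estimated correlation), but 1 of 44 passed, Thbs2 (0.74), with 4 higher when adjusted over the list alone. Macrophage markers were higher (mean 0.37, camera adjusted p = 4.83e-05; adjusted p = 0.619 with an estimated correlation), with none of 25 passing and 2 higher when adjusted over the list alone. Cardiomyocyte markers were lower (mean -0.105, camera adjusted p = 0.00491; adjusted p = 0.619 with an estimated correlation), with none of 16 passing, and 1 higher and 5 lower when adjusted over the list alone. Without R172K 4 the macrophage and cardiomyocyte calls ended, with a mean of 0.12 (adjusted p = 0.217) for macrophage and -0.03 (adjusted p = 0.127) for cardiomyocyte markers. Epicardial and mesothelial markers were higher (mean 0.53, camera adjusted p = 6.32e-05; adjusted p = 0.619 with an estimated correlation), with Upk1b passing among 12 and 5 higher when adjusted over the list alone. Fibroblast markers were higher (mean 0.32, camera adjusted p = 0.000928; adjusted p = 0.619 with an estimated correlation), with Pdgfra (0.75) passing among 21 by either adjustment. Interferon-stimulated genes were lower in R172K than in R140Q hearts (mean -0.26, camera adjusted p = 0.000461; adjusted p = 0.619 with an estimated correlation), with none of 22 passing and 3 lower when adjusted over the list alone. Against control, their mean was 0.20 in R140Q hearts (camera adjusted p = 0.00261; adjusted p = 0.628 with an estimated correlation), with 1 gene higher by either adjustment, and -0.05 in R172K hearts (camera adjusted p = 0.735). The R140Q call ended without control 1 (mean 0.12, adjusted p = 0.0592). Endothelial markers were lower in R172K than in R140Q hearts (mean -0.14, camera adjusted p = 0.00521; adjusted p = 0.619 with an estimated correlation), with none of 22 passing and 4 lower when adjusted over the list alone. Against control they were higher in R172K hearts too (mean 0.16, camera adjusted p = 0.0099; adjusted p = 0.546 with an estimated correlation), where Kdr (0.53) and Esam (0.43) rose by either adjustment. That call ended without R172K 3 (0.0755), R172K 4 (0.0605), the dimmer genes (0.0652) or control 3, R172K 3 and R140Q 4 together (0.0537). Atrial markers were higher (mean 1.04, camera adjusted p = 0.00521; adjusted p = 0.619 with an estimated correlation), with Myl4 passing among 13 and 2 higher when adjusted over the list alone, and had a camera adjusted p of 0.0882 without R172K 3 and 0.0512 without the dimmer genes. Without R172K 4 the mean was 0.30 for extracellular matrix genes (camera adjusted p = 0.0132) and 0.19 for fibroblast markers (0.0401). Without R172K 2 it was -0.16 for interferon-stimulated genes (0.0206). The mean of the atrial list in log2 intensity was 8.26 ± 0.89 in control, 7.41 ± 0.23 in R140Q and 8.45 ± 0.44 in R172K hearts (SD, n = 4).

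The number of genes between the mutants depended strongly on single arrays. It was 1577 without R172K 3, 1 without R172K 1, 5 without R172K 2, 5, 180, 45 and 1 without R140Q 1, 2, 3 and 4, and 118, 93, 108 and 101 without control 1, 2, 3 and 4, and none of the 20 largest passed in every case. It was 9 in a fit of the 8 mutant arrays alone. With each array centred on its median the split was 78 higher and 330 lower in place of 97 and 199.

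A few genes stood out in single arrays or in part of a group, and they were chosen after their values were seen. The surfactant gene Sftpc, a marker of lung epithelium, lay at 11.57 in R140Q replicate 4 and at most at 5.51 in the other 11 arrays. Myl7 was highest in control replicate 3 (12.49) and R172K replicate 3 (11.36). The major histocompatibility class II gene H2-Ea lay between 5 and 5.28 in the control arrays, at 8.37, 4.96, 8.76 and 6.71 in R140Q replicates 1 to 4, and at 8.77, 7.18, 5.07 and 4.98 in R172K replicates 1 to 4. Without control 3, R172K 3 and R140Q 4 together, a choice made after seeing the data, the counts were 354 genes for R140Q against control, 3442 for R172K against control and 806 between the mutants.

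**Figure D4:**
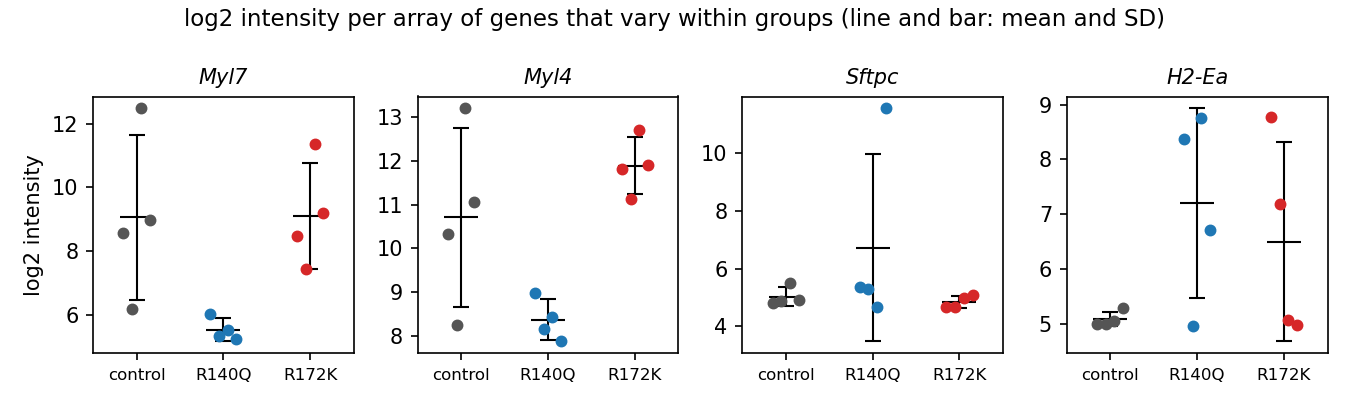
Log2 intensity (vertical axes, which do not start at 0) of Myl7, Myl4, Sftpc and H2-Ea in each of the 12 arrays by group, with points for arrays. Sftpc lies at 11.57 in R140Q replicate 4 and at most at 5.51 elsewhere.

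The mean of both mutants against control gave 1834 changed genes, 864 higher and 970 lower, or 9.2% of all genes tested. The largest changes named were those of Nmrk2 (3.88), Timp1 (2.41), Postn (2.24), Lox (2.18) and Nppb (2.02) upward and of Ces1d (-3.21), Cabcoco1 (-2.55), Lgi1 (-2.55), Slc38a4 (-2.12), As3mt (-1.81), the ribosomal protein gene Rpl3l (-1.70), which is specific to muscle, the dehydrogenase gene Dhdh (-1.69) and the GABA receptor subunit Gabrg3 (-1.68) downward. Extracellular matrix genes rose in 18 of 44 cases with none lower (camera adjusted p = 6.18e-15; adjusted p = 0.551 with an estimated correlation), and 35 were higher when adjusted over the list alone. Calcium handling and ion channel genes fell in 8 of 23 cases with none higher (camera adjusted p = 4.28e-07; adjusted p = 0.551 with an estimated correlation), and 13 were lower when adjusted over the list alone. The count was 721, 683, 1038 and 1112 without control 1, 2, 3 and 4, 1208 without R140Q 3 and 3333 without R172K 3. Timp1 (adjusted p up to 0.0636), Postn (up to 0.0642) and Ces1d (up to 0.0567) failed without control 1 or 2, and Lox (up to 0.0694) failed without any 1 control array.

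The changes in both mutants were compared across genes, which are not independent replicates and share the 4 control arrays. Across 19937 genes Pearson's r was 0.720. Unchanged groups simulated with shared controls gave a mean r of 0.5, which 3 groups of equal size give by design. That simulation drew the control arrays too, with noise independent between genes and the same SD in all arrays. Real genes varied together, with an estimated correlation of 0.671 among extracellular matrix genes. Both r and the covariance may therefore vary more by chance than the simulation shows. The covariance was 0.0507 against a simulated 0.00768, a difference of 0.0430. With the controls split so that each mutant had its own pair, r averaged 0.573 over 6 splits, from 0.462 to 0.685. Of the changed genes, 134 were higher in both mutants and 180 were lower in both, an overlap that was not tested against shared controls. Of the 314 genes that changed in both contrasts under limma, 0 did so in opposite directions. Shared controls favour equal signs, since simulated unchanged groups had the same sign in 66.6% of genes on average. The genes with an unadjusted limma p under 0.05, 3394 for R140Q and 5302 for R172K, were not compared for direction.

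**Figure D5:**
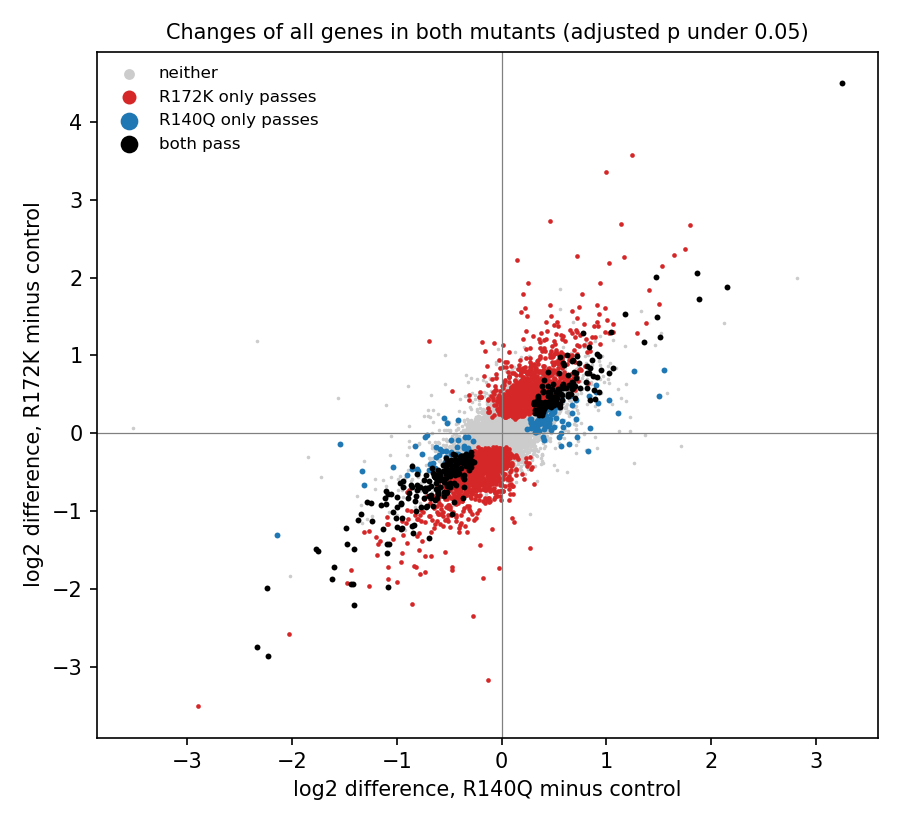
Log2 difference from control of 19937 genes in R140Q (horizontal axis) and R172K hearts (vertical axis), coloured by whether the adjusted p was under 0.05 in neither, one or both mutants. The 134 genes higher in both and 180 lower in both lie in the upper right and lower left, and Pearson's r across genes is 0.720.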

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

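The tests of the atrial share, of Myl4 at equal Myl7 and of a general shift of the array with lung transcripts were chosen only after the result was seen.

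Between R172K and R140Q hearts 296 genes changed in the direct test. Another split of the 8 mutant arrays, which exchanged R140Q replicate 3 and R172K replicate 3, gave 391 genes, so 2 of 35 splits gave as many and chance cannot be excluded. For R140Q against control the real split gave 439 genes and the highest other split 1. So 1 of 35 splits gave as many, the smallest share that 35 splits allow, which argues against chance but does not exclude it. For R172K against control these were 2593 and 1, again 1 of 35. For the mean of both mutants they were 1834 and 620, with 1 of 100 splits giving as many.

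The atrial markers were higher in R172K than in R140Q hearts by a mean of 1.04. A different share of atrial tissue may account for part of this: the median r of the other 12 list genes with Myl7 within groups was 0.664, but it was 0.246 without control 3 and R172K 3, so the median rests on those arrays. Of 12 relations tested by permutation, 3 had an adjusted p under 0.05, and without those arrays their r was 0.945 for Myl4 (from 0.95), 0.756 for Sln (from 0.927) and 0.75 for Dkk3 (from 0.888). At equal Myl7, Myl4 differed by 1.134 between R172K and the other 8 arrays, which decides nothing, since Myl4 was singled out for its difference. The share of atrial tissue and a higher Myl4 level stay open, and a difference between the mutants in atrial muscle itself was not tested apart from them.

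Lung transcripts stood out in R140Q replicate 4, where 5 of 5 lung genes of the fixed list lay above all other arrays. Its median difference over all genes was 0.00227, which says nothing about a general shift, since RMA had set the arrays to a similar distribution. For lung tissue in the sample, 12 lung genes outside the list had a median difference of 0.182, against at most 0.07 in another array, which lay far below the 1 log2 set beforehand for lung tissue and below the bound of 0.2 set against it, by less than the SD of 0.0553 over the other 11 arrays. The SD was taken into account only after the value was seen, and on that reading the median does not decide about lung tissue. A median does not show single genes: the 12 differences ran from -0.23 for Hopx to 2.64 for Lamp3, with 1.55 for Cldn18. In the fixed list the difference of Sftpc was 6.59. Of these 12 genes 6 lay above all other arrays, a count chosen after the values were seen.

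H2-Ea was high in some mutant arrays and between 5 and 5.28 in all control arrays. More antigen-presenting cells are argued against, since the median slope of 6 other class II genes on H2-Ea within the mutant groups was -0.108. A segregating haplotype of the mixed strain background may be a source, but the test did not decide: of the 50 genes that followed H2-Ea most closely 10% lay on chromosome 17, against 4.72% of all genes. Against control its difference was 2.12 in R140Q (limma adjusted p = 0.233) and 1.42 in R172K hearts (adjusted p = 0.340), and neither passed.

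Single arrays far from the other 3 of their group were found in 14 of 294 groups tested, and chance gives about 5%. The gap to the nearest array, as a share of the group's range, was 0.877 for Sntb1 and 0.903 for Slc38a1 in control replicate 4, and 0.917 for Sh3bgr and 0.853 for the mean of the autophagy list in control replicate 1. In R140Q hearts it was 0.878 for Mybl1 and 0.843 for the muscle atrophy list in replicate 2, 0.945 for Lox in replicate 3 and 0.859 for the smooth muscle and pericyte list in replicate 4. In R172K hearts it was 0.936 for Cabcoco1 and 0.933 for Cfap20dc in replicate 3, and 0.902 for Armh4 in replicate 2. In R172K replicate 4 it was 0.929 for Idh2, 0.875 for the adult contractile list and 0.896 for the immediate early list.

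Among 13120 probe sets with no gene symbol or several, fitted and adjusted on their own, 182 changed between R172K and control hearts, 84 of them higher. Of the same probe sets, 0 passed limma's test between R140Q and control.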

How the results depend on the processing

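The fit without 3 arrays and the Myl7 covariate were chosen after seeing the data. Among the calls of named genes (295) and of lists (62), 0 reversed direction under the alternatives run for them. For many calls this was fixed in advance. The stricter thresholds keep the same log2 differences and cannot reverse any. The largest changes named were chosen for groups that did not overlap, so leaving out 1 array could not reverse them either. With only the groups compared in the fit, 1342 genes changed for R140Q against control, 1788 for R172K against control and 9 between the mutants. With the replicate number as a block they were 196, 2014 and 11, although the numbers do not pair the arrays (2 of 12 pairs of one number correlated above 0.1). With every probe set on its own they were 271, 2647 and 5. Between the mutants, 449 genes passed without the dimmer genes and 179 with a trended, robust variance. Array weights gave 1651 for R140Q, 4491 for R172K, 1774 between the mutants and 3802 for the mean of both, with weights of 0.365 for R172K 3 and 0.366 for R172K 4. Requiring at least 2-fold gave 55, 242, 21 and 121, and an adjusted p under 0.01 gave 73, 773, 1 and 436, since both thresholds are stricter. Without 3 arrays 806 genes differed between the mutants. With the Myl7 covariate the counts were 113 for R140Q, 125 between the mutants and 951 for the mean of both. Leaving out 1 array gave 100 to 1015 genes for R140Q, 1327 to 4157 for R172K, 1 to 1577 between the mutants and 683 to 3333 for the mean of both. For the other alternatives the cause was not tested.

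Idh2 in the mean of both mutants passed with array weights (-0.296, adjusted p = 0.0329), and ranged from -0.37 to -0.246 when 1 array was left out, passing without R172K 4 (adjusted p = 0.048). The correlation between the mutants was 0.573 with the controls split. With an estimated correlation 0 of 62 camera list calls passed, 21 of 62 were lost without R172K 4, the most for any 1 array, and 18 of 59 were lost without the dimmer genes. Probe sets could not be filtered by suffix, as their names have none, and no covariate for Y-linked genes was run, since these were high and Xist low in all 12 arrays. Values near the arrays' background limit what can be said of dim genes.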

Other observations

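Circadian clock genes were not called as a list in R172K hearts (camera adjusted p = 0.463), yet 2 of 18 rose and 5 fell, with Arntl, a core activator of the clock, higher by 1.24 and Hlf (-1.22), Tef (-0.81) and Per3 (-0.73) lower. Adjusted over the list alone, 5 were higher and 7 lower. The times of dissection are not given in the sources used here. Of 32 targets of ATF4 and the mitochondrial stress response, 6 rose and 3 fell (camera adjusted p = 0.137), with Mthfd2, a mitochondrial folate enzyme, higher by 1.01, and 12 higher and 5 lower when adjusted over the list alone. Immediate early genes were higher as a list in R140Q hearts (mean 0.50, camera adjusted p = 0.000701; adjusted p = 0.628 with an estimated correlation), with Nr4a3 passing among 22 and 3 higher when adjusted over the list alone. They were also higher in R172K hearts (mean 0.46, camera adjusted p = 0.0107; adjusted p = 0.667 with an estimated correlation), with 4 of 22 higher, such as the nuclear receptor gene Nr4a1 (1.28), and 6 when adjusted over the list alone. The R172K call ended without R172K 4 (adjusted p = 0.0605), control 2 (0.051) or the dimmer genes (0.0717). The R140Q mean ran from 0.371 to 0.871 over 19 alternatives other than the estimated correlation, and the list was called in all 19.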
